A study of Mus musculus with 53 samples.

How the data were processed

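The series holds 53 samples of mouse embryonic fibroblasts, wild type (WT) or knocked out for Anp32e (KO). The 22 RNA libraries were analysed here: 10 from cells given decitabine (DAC) or DMSO (2 WT DMSO, 2 KO DMSO, 3 WT DAC, 3 KO DAC) and 12 from cells given an siRNA against H2A.Z or a control siRNA labelled NT (3 libraries per group). The 31 CUT&Tag samples, which profile H2A.Z, H3K9me3 and H3K27ac, were not analysed here, since only the RNA tables were used.

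The deposited DAC table gives FPKM and the deposited siRNA table gives RPKM, both computed by the authors. Per the submitters' processing notes STAR, Bowtie2, deepTools and the mm10 assembly were used. Their versions, the read counter, the annotation, the strand setting and the reads that make up the scaling total are not given in the sources used here. Each table lists 43432 Ensembl genes, of which 42462 (97.8%) carry a symbol. A symbol was listed more than once in 20 cases, and the entry with the highest mean stood for the gene. No entries for repeat families such as IAP elements were found, so repeats were not measured. Genes with near-identical copies (Plac9a and Plac9b, Prl2c2 and Prl2c3, Rps4l, Rps3a3, H2-Q6, Xlr3b and members of the Oas family) are uncertain, since the handling of reads that fit several places is not stated.

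Library totals and gene lengths were solved from the smallest steps between values, and all 35023 genes above 0 then gave whole read numbers within 0.01. Totals were 27503472 to 36910532 reads in the DAC table and 31928320 to 47172427 in the siRNA table. At this depth 1 read in a gene of 1 kb corresponds to 0.0271 to 0.0364 FPKM and 0.0212 to 0.0313 RPKM. The 7SL RNA genes took 0.95 to 1.69% of reads in the DAC table, 14.1 to 16.34% in the WT siRNA libraries and 17.95 to 21.6% in the KO siRNA libraries, and the 10 highest genes 13.5 to 15.64% and 20.54 to 31.19%. Because shares of this size enter the scaling total, a median-centred scaling was run as an alternative. The first principal component held 46.7% of the variance in the DAC table and 73.3% in the siRNA table.

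Genes with a value of at least 1 in at least 2 libraries (DAC table, 16434 genes) or 3 libraries (siRNA table, 12668 genes) were tested. Each table was fitted once, with its 4 groups, on log2 of the value plus 1, using limma 3.58.1 under R 4.3.3 with an intensity trend. Contrasts were KO against WT under each condition, treatment against control in each genotype, and the interaction, which is the treatment effect in KO minus that in WT. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a contrast. Gene positions in mm10 were matched for 14656 (89.2%) and 12157 (96.0%) of the tested genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the other steps.

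For the lists, 27 were written before the data were examined: H2A.Z deposition and removal, DNA and H3K9 methylation silencing, germline genes silenced by promoter methylation, imprinted genes, interferon-stimulated genes, p53 targets, G2/M, S phase, collagen and matrix, smooth muscle and myofibroblast, inflammatory and senescence-secreted genes, immediate early genes, cholesterol synthesis, unfolded-protein and amino-acid stress, glycolysis and hypoxia, Hox genes, pluripotency, macrophage, endothelial, skeletal muscle, neural and glial, epithelial, chondrocyte and bone, adipocyte, erythroid, sex-linked and mitochondrially encoded genes. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over lists and contrasts of a table. Camera with an estimated correlation and fry were run beside it, and fry tests only whether a list's genes move, on balance, one way. Members were also adjusted over the list alone.

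Named genes followed a fixed rule. Anp32e, H2afz and H2afv were named in every comparison. Up to 8 higher and 8 lower genes per comparison (4 each for interactions) were those with the largest change among called genes. They needed a mean of at least 5 in the higher group and no overlap between the libraries of both groups. For interactions the mean was that of the highest group, and the condition of no overlap was dropped. Predicted genes, clones, small RNAs and ribosomal pseudogenes were left out. Up to 2 higher and 2 lower called members per list were added. The text prints part of these. Mesothelial markers, Y-linked genes, Tsix and chromosome medians were added after the data were seen.

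Alternatives fixed beforehand were a pseudocount of 0.1, no filter, a filter at 5, median centring, replicate number as a block, only the libraries of the groups compared, all entries of repeated symbols, a 2-fold minimum, and leaving out each library in turn. Where that left 1 library in a group, it was assumed to vary like the other groups. Chosen after the data were seen were limma-voom on the recovered reads, the same with median-ratio totals, leaving out both libraries of a table that stand apart, and centring each chromosome. Replicate numbers were checked as a pairing by the correlation of deviations from group means. They paired KO NT with KO H2AZ siRNA, where equal numbers correlated at 0.14 to 0.27 and different ones at −0.25 to 0.06. This pairing comes from the data, since the labels name no shared culture or day. A fit of those groups alone with the replicate block was added for that comparison.

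The test was checked on simulated counts with the depths of these libraries and a single dispersion per table (0.00312 and 0.00275), taken from well-covered genes. Libraries that stand apart and the larger spread of some genes were not simulated, so recovery in the real data may be lower. Of genes changed 1.5-fold, 61.1% were recovered for KO against WT in DMSO, 35.8% for the DAC interaction, 91.9% for KO against WT with NT siRNA, 96.0% for H2AZ siRNA in KO and 78.8% for the siRNA interaction. For 2-fold changes these were 86.3, 72.6, 98.0, 98.0 and 96.0%. False calls numbered 7, 8, 13, 8 and 11 among 15450 (DAC) or 12319 (siRNA) genes.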

Results

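RNA was sequenced from mouse embryonic fibroblasts that were wild type (WT) or labelled as a knockout of Anp32e (KO), the gene of a histone chaperone that removes the variant H2A.Z from chromatin. In one table, in FPKM, the cells had received decitabine (DAC), an inhibitor of DNA methyltransferases, or its solvent DMSO: 2 WT DMSO, 2 KO DMSO, 3 WT DAC and 3 KO DAC libraries. In the other table, in RPKM, they had received an siRNA against H2A.Z (H2AZ siRNA) or a control siRNA labelled NT, with 3 libraries in each of 4 groups. Depth ran from 27503472 to 36910532 reads per library in the DAC table and from 31928320 to 47172427 in the siRNA table. Replicates correlated across genes at 0.9897 to 0.993 in the DAC table and 0.996 to 0.9974 in the siRNA table, where genes are not independent replicates. WT DAC replicate 3 and KO DAC replicate 1 stood apart from the other two libraries of their groups, as did WT NT replicate 1 and KO NT replicate 1. The labels call the libraries biological replicates, except those of KO H2AZ siRNA, which are labelled only as replicates. Nothing in the sources used here says whether they are separate cultures, so every p-value measures the spread between samples only. The comparisons, the rule for naming genes, 27 gene lists and most of the other settings tried were fixed before the data were examined. All p-values across genes come from limma, with a Benjamini-Hochberg adjustment within each comparison. A gene is said to have risen, fallen or changed only when its adjusted p was under 0.05. Levels are given as mean ± SD over libraries, and log2 fold changes as estimate ± standard error.

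Anp32e (ENSMUSG00000015749, chromosome 3, 95929245 to 95947387 in the mm10 assembly) was at 14.5 ± 0.0299 FPKM in WT DMSO (n = 2), 15.7 ± 1.57 in WT DAC (n = 3), 5.09 ± 0.313 in KO DMSO (n = 2) and 6.96 ± 0.577 in KO DAC (n = 3). In the siRNA table, which was normalised separately, it was at 19.3 ± 1.77 RPKM in WT NT, 18.4 ± 1.35 in WT H2AZ siRNA, 5.07 ± 0.578 in KO NT and 5.37 ± 0.908 in KO H2AZ siRNA (n = 3 each). Anp32e was lower in KO under all 4 conditions, by limma log2 fold changes of −1.35 ± 0.10 in DMSO (adjusted p = 1.1e-05), −1.07 ± 0.08 in DAC (adjusted p = 5.5e-05), −1.74 ± 0.11 with NT siRNA (adjusted p = 1.6e-07) and −1.61 ± 0.11 with H2AZ siRNA (adjusted p = 3.1e-07). In every condition each KO library lay below each WT library. Transcript of Anp32e was thus lower but still present in every KO library, and the sources used here do not describe the knockout allele, so it is open whether KO cells were without the protein. DAC raised it in KO by 0.38 ± 0.09 (limma adjusted p = 0.0089), a call that ended without KO DMSO replicate 2 (0.33). The median of all chromosome 3 genes in that comparison was 0.21, so part of this rise was shared by the chromosome. Anp32e did not pass the threshold with DAC in WT or with H2AZ siRNA in either genotype.

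H2afz (ENSMUSG00000037894, chromosome 3, 137864487 to 137866922), the gene of the main H2A.Z isoform, was at 202 ± 2.56 RPKM in WT NT, 17.2 ± 0.476 in WT H2AZ siRNA, 194 ± 8.49 in KO NT and 27.9 ± 2.18 in KO H2AZ siRNA. H2AZ siRNA lowered it by a log2 fold change of −3.48 ± 0.05 in WT (limma adjusted p = 7.0e-12) and −2.75 ± 0.05 in KO (adjusted p = 9.9e-11), and under H2AZ siRNA it was higher in KO than in WT by 0.67 ± 0.05 (adjusted p = 1.5e-06). H2afv (ENSMUSG00000041126, chromosome 11, 6427226 to 6444511), the second H2A.Z gene, was at 17.2 ± 1.75, 1.57 ± 0.103, 22.5 ± 1.04 and 3.01 ± 0.803 RPKM in the same 4 groups. It fell with H2AZ siRNA by −2.82 ± 0.12 in WT (adjusted p = 8.4e-08) and −2.57 ± 0.12 in KO (adjusted p = 2.4e-07), and it was higher in KO by 0.37 ± 0.12 with NT siRNA (adjusted p = 0.014) and 0.63 ± 0.12 with H2AZ siRNA (adjusted p = 6.3e-04). The NT siRNA call ended without WT NT replicate 2 (0.31, adjusted p = 0.06) or KO NT replicate 3 (0.34, adjusted p = 0.0504). In the DAC table H2afz was at 101.3 ± 3.06 FPKM in WT DMSO, 106 ± 18.3 in WT DAC, 85.2 ± 4.65 in KO DMSO and 117 ± 17.4 in KO DAC. It did not pass the threshold there, although without KO DAC replicate 1 its rise with DAC in KO did (0.57, limma adjusted p = 0.0151). H2afv was at 27 ± 2.72, 18.9 ± 2.09, 30.7 ± 1.24 and 19 ± 0.817 FPKM in those groups and fell with DAC by −0.50 ± 0.10 in WT (adjusted p = 0.0054) and −0.67 ± 0.10 in KO (adjusted p = 5.9e-04). The WT call ended without WT DMSO replicate 2 (−0.40, adjusted p = 0.0608).

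**Figure D1:**
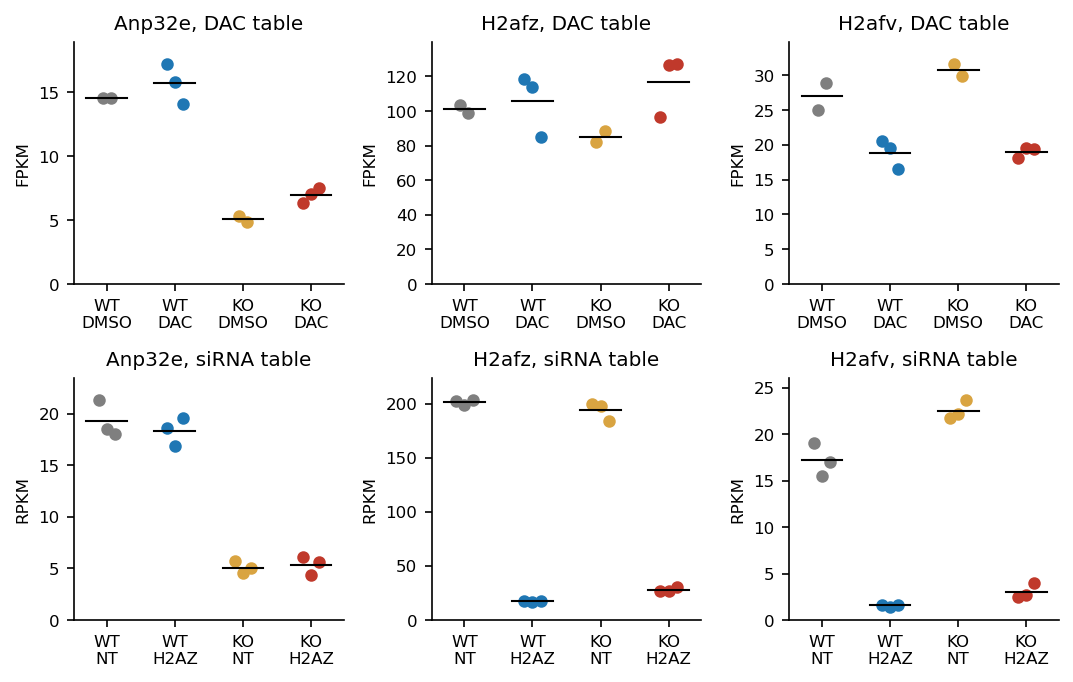
Anp32e, H2afz and H2afv in every library, with bars at group means; Anp32e averaged 14.5 FPKM in WT DMSO and 5.09 in KO DMSO, and H2afz 202 RPKM in WT NT and 17.2 in WT H2AZ siRNA. The tables were normalised separately.

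Comparing KO with WT in DMSO asks which genes differ between the genotypes in otherwise untreated cells. Y-linked genes were present in every KO library and near absent in every WT library of both tables, as given below. By these genes, and by Xist in DMSO and NT siRNA, WT cultures were female and KO cultures male. Every difference between KO and WT in this report, the interactions included, thus holds a difference of sex and origin as well as the knockout. These data do not separate them. Of 16434 genes tested, 3219 were higher and 3757 lower in KO (2 libraries per group), 997 and 716 of them by at least 2-fold. Large rises were found for genes that mark mesothelium, the lining of the body cavities. Upk3b averaged 0.082 ± 0.0373 FPKM in WT and 384 ± 17.1 in KO (log2 fold change 8.47 ± 0.44, adjusted p = 1.3e-06), Podxl 1.74 and 287 (6.72 ± 0.16), and Wt1 0.0155 and 61.4 (5.94 ± 0.12). Gpm6a was listed at 0 in both WT libraries and at 102 in KO. The transcription factor gene Tbx5 fell from 28 to 0.231 FPKM (−4.56 ± 0.12), the Wnt regulator Sfrp2 from 174 to 8.22 (−4.25 ± 0.15), and the opioid precursor Penk from 104 to 6.68 (−3.76 ± 0.18). Xist, the RNA that coats the inactive X chromosome, was at 175 in WT and 0.751 in KO (−6.66 ± 0.26), which goes with the difference in sex. The matrix gene Dcn rose from 10.3 to 159 FPKM (3.83 ± 0.14) and the imprinted H19 from 30.8 to 328 (3.37 ± 0.20), whereas the imprinted Plagl1 fell from 140 to 17.6 (−2.93 ± 0.32).

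By gene list in KO against WT with DMSO, 29 of 35 measured interferon-stimulated genes fell and 1 rose (median −0.915, limma camera adjusted p = 1.2e-11). Isg15 fell from 97.1 to 20.6 FPKM and Rtp4 from 61.7 to 11.7, and Rsad2 was the member that rose (0.54 ± 0.11). Of 29 p53 target genes 21 fell and 3 rose (median −0.847, adjusted p = 2.18e-05). Cdkn1a fell from 44.8 to 9.58 FPKM (−2.11 ± 0.14) and Gadd45a rose (2.06 ± 0.17). For these lists the values were adjusted p = 0.0983 and adjusted p = 0.146 with an estimated correlation. Cholesterol synthesis genes fell in 19 of 21 cases with no rise (median −0.632, adjusted p = 2.39e-07), Fdps from 74.9 to 26.7 FPKM. Glycolysis and hypoxia genes rose in 17 of 21 with 1 lower (median 0.823, adjusted p = 1.7e-06), Egln3 from 0.483 to 9.04. Their values were adjusted p = 0.321 and adjusted p = 0.315 with an estimated correlation. Smooth-muscle and myofibroblast genes (10 of 17 lower, 3 higher, median −0.608, adjusted p = 0.0162), fibrillar collagen and matrix genes (18 of 27 lower, 6 higher, −0.363, adjusted p = 0.023) and G2/M genes (13 of 27 lower, 1 higher, −0.283, adjusted p = 0.0314) also passed as lower. Acta2 fell from 195 to 38 FPKM and Col5a2 from 139 to 39.9. Epithelial markers (4 of 8 higher, 0 lower, median 0.841, adjusted p = 0.00594) and sex-linked genes (4 of 5 higher, 1 lower, 1.845, adjusted p = 0.0194) passed as higher. Among the epithelial genes that rose, Krt7 (3.123) and Krt18 (3.938) are also mesothelial markers, most of which were higher in KO DMSO. The sex-linked members that rose were Y-linked and the one that fell was Xist. Those 5 lists had adjusted p = 0.277 to 0.548 with an estimated correlation. Adjusted over the list alone, G2/M genes gave 15 lower and smooth-muscle genes 11 lower, with the other 7 called lists unchanged in their counts.

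No shift of the whole list was detected in DMSO for DNA-methylation and H3K9-methylation silencing genes (7 of 24 higher, 3 lower, median 0.058, adjusted p = 0.245), imprinted genes (10 of 21 higher, 6 lower, 0.311, 0.277), S-phase genes (2 of 32 higher, 7 lower, −0.109, 0.284), inflammatory and senescence-secreted genes (10 of 25 higher, 6 lower, 0.182, 0.353). Nor was one for unfolded-protein and amino-acid stress genes (6 of 22 higher, 3 lower, 0.042, 0.245) or mitochondrially encoded genes (2 of 13 higher, 0 lower, 0.49, 0.0535). The same held for endothelial markers (2 of 7 higher, 5 lower, −0.736, 0.19), chondrocyte and bone markers (1 of 9 higher, 5 lower, −0.482, 0.106), adipocyte markers (1 of 5 higher, 4 lower, −0.86, 0.145) and neural and glial markers (2 of 5 in each direction, 0.348). For 4 lists the median, mean and test differed in sign. These were H2A.Z deposition and removal genes (4 of 18 higher, 1 lower, median −0.014, test upward, 0.764, with the median at 0.019 after median centring) and germline genes silenced by promoter methylation (0 of 12 higher, 1 lower, median 0.001, mean −0.107, 0.941). The others were immediate early genes (6 of 18 higher, 5 lower, median 0.035, mean −0.001) and Hox genes (11 of 24 in each direction, median −0.202, mean 0.181, test upward, 0.735). Within the Hox list Hoxb9 rose from 0.25 to 11 FPKM (3.27 ± 0.08) while Hoxd13 fell from 128 to 42.3 (−1.58 ± 0.10). Too few members were measured for a test of pluripotency genes (Nanog higher, Sox2 lower), macrophage markers (4 measured, Csf1r higher, Cd14 lower), skeletal-muscle markers (Des higher) and erythroid markers (Alas2, which did not pass).

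DAC against DMSO in WT asks which genes respond when DNA methyltransferases are inhibited in WT cells. It raised 2384 genes and lowered 2274 (3 against 2 libraries), 319 and 277 by at least 2-fold. Without WT DMSO replicate 2 the counts were 1325 and 1166. Apob, the gene of the main lipoprotein of liver and gut, rose from 0.334 to 30.6 ± 2.01 FPKM (4.57 ± 0.10, adjusted p = 1.4e-07). Rises were also large for the sensors of foreign nucleic acid Oas3, from 0.314 to 16.2 (3.71 ± 0.07), and Zbp1, from 2.46 to 30.3 (3.17 ± 0.12). The secreted matrix protein gene Spp1 rose from 161 to 746 FPKM (2.22 ± 0.10), the chemokine Ccl2 from 9.20 to 50.8 (2.35 ± 0.08) and the X-linked homeobox gene Rhox5 from 0.298 to 6.54 (2.52 ± 0.19). Among the genes that fell were Sfrp2, from 174 to 32.5 FPKM (−2.39 ± 0.14), the chemokine Cxcl12, from 156 to 47.6 (−1.69 ± 0.08), Igfbp5, from 23.7 to 4.98 (−2.04 ± 0.14), and the imprinted Mest, from 17.1 to 3.83 (−1.91 ± 0.16).

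Germline genes rose with DAC in WT in 9 of 12 cases with none lower (median 0.605, camera adjusted p = 2.65e-06), as did 29 of 35 interferon-stimulated genes with none lower (0.88, adjusted p = 2.22e-19). So did 21 of 29 p53 targets with 1 lower (0.578, adjusted p = 1.01e-09) and 17 of 25 inflammatory genes with 3 lower (1.002, adjusted p = 9.79e-08). Imprinted genes went the other way, 9 of 21 lower and none higher (−0.193, adjusted p = 0.000828), Peg10 falling from 61.8 to 18.1 FPKM. Each of these 5 lists had adjusted p = 0.0983 with an estimated correlation. A germline gene near absent in DMSO passed the filter only if DAC raised it. This partly fixed the germline counts here and below. Glycolysis and hypoxia genes (16 of 21 higher, 0.574, adjusted p = 2.55e-07), G2/M genes (8 of 27 higher, 0.161, adjusted p = 0.00219), stress genes (7 of 22 higher, 0.249, adjusted p = 0.00427) and epithelial markers (5 of 8 higher, 0.799, adjusted p = 0.0103) passed with no member lower. Collagen and matrix genes passed downward (18 of 27 lower, 4 higher, −0.565, adjusted p = 5.63e-05), Postn falling from 58.5 to 17.9 FPKM. These had adjusted p = 0.277 to 0.413 with an estimated correlation. Immediate early genes split into 9 lower and 7 higher of 18, Fos falling from 119.8 to 46.7 FPKM and Fosl1 rising from 11 to 56. Among DNA-methylation genes Tet1 (−1.15 ± 0.10) and Dnmt3a (−0.56 ± 0.10) fell. The risen counts adjusted over the list alone were 10 germline, 31 interferon-stimulated, 22 p53 and 18 glycolysis genes, with the other called lists as given.

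DAC against DMSO in KO asks the same in KO cells. With DAC 3889 genes were higher and 3542 lower (3 against 2 libraries), 583 and 913 by at least 2-fold. The KO DMSO libraries lay at 66.2 and 66.8 on the first principal component, and all others from −29.9 to −1.9. Chromosome medians had an SD of 0.1174 here against 0.0345 for DAC in WT. A difference between the KO DMSO and KO DAC cultures other than the drug thus cannot be told apart from DAC. This holds for the genes and the lists of this comparison. Apob rose from 0.917 to 47.2 FPKM (4.65 ± 0.10, adjusted p = 4.5e-08), Oas3 from 0.548 to 30.5 (4.35 ± 0.07), Oas2 from 3.63 to 46.1 (3.35 ± 0.09), Rhox5 from 0.0427 to 11.9 (3.61 ± 0.19) and the cell-cycle inhibitor Cdkn1a from 9.58 to 70.5 (2.75 ± 0.13). Xist rose from 0.751 to 33.9 ± 9.06 FPKM (4.29 ± 0.23, adjusted p = 1.8e-06), with 0.923 and 0.579 in the DMSO libraries and 44.4, 28.9 and 28.5 in the DAC libraries. Tsix, its antisense gene, was at no more than 0.00046 of Xist in KO DAC, although the strand setting of the counts is not given. Several genes that fell had been low in WT. Fras1 went from 49.5 to 1.01 FPKM (−4.66 ± 0.09), Plxna4 from 49.5 to 1.35 (−4.43 ± 0.10) and the retinoic-acid enzyme gene Aldh1a2 from 37.2 to 1.39 (−4.00 ± 0.11), against 0.988, 0.0426 and 0.17 in WT DMSO. Igfbp3, at 7.03 in WT DMSO, fell from 67.4 to 2.13 (−4.46 ± 0.09).

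All 35 interferon-stimulated genes rose with DAC in KO (median 1.918, camera adjusted p = 4.24e-21), as did 11 of 12 germline genes with none lower (1.554, adjusted p = 1.88e-07) and 23 of 29 p53 targets with 3 lower (1.086, adjusted p = 1.22e-08), all 3 lists at adjusted p = 0.0983 with an estimated correlation. As in WT, germline genes near absent in DMSO passed the filter only where DAC raised them. G2/M genes (22 of 27 higher, 1 lower, 0.496, adjusted p = 1.88e-07), cholesterol genes (10 of 21 higher, 2 lower, 0.188, adjusted p = 0.00544), smooth-muscle genes (11 of 17 higher, 3 lower, 0.499, adjusted p = 0.0271) and sex-linked genes (5 of 5 higher, 0.641, adjusted p = 0.00311) also passed upward. Acta2 rose from 38 to 149 FPKM. Collagen genes (13 of 27 lower, 5 higher, −0.286, adjusted p = 0.00451), immediate early genes (11 of 18 lower, 4 higher, −0.594, adjusted p = 0.0404) and mitochondrially encoded genes (5 of 13 lower, 0 higher, −0.537, adjusted p = 0.0205) passed downward. Eln fell from 19.8 to 0.578 FPKM and Fos from 129.9 to 23.9. These 7 lists had adjusted p = 0.273 to 0.643 with an estimated correlation. Imprinted genes (11 of 21 lower, 5 higher, median −0.393) and Hox genes (11 of 24 higher, 10 lower, median 0.065, mean −0.163) were not called, H19 falling from 328 to 75.1 FPKM. Over the list alone, adjusted counts were 25 p53, 23 G2/M and 11 cholesterol genes higher and 16 collagen genes lower, with the other called lists as given.

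KO against WT in DAC asks how the genotypes differ once both are treated. KO was higher for 1828 genes and lower for 1902 (3 libraries per group), 191 and 172 by at least 2-fold. Upk3b was at 0.718 ± 1.16 FPKM in WT and 32.9 ± 2.93 in KO (4.50 ± 0.36, limma adjusted p = 6.9e-05), with WT DAC replicate 3 carrying most of the WT signal. That library also carried most of the WT DAC signal of the mesothelial markers Gpm6a (0.318), Upk1b (0.388) and Wt1 (0.212), but not of Aldh1a2 or Bnc1. The limb gene Tbx4 was at 0.132 in WT and 14.9 in KO (3.81 ± 0.09). The germ-cell genes Dazl, at 0.321 and 2.51 FPKM (1.41 ± 0.10, adjusted p = 3.9e-05), and Tex19.1, at 0.487 and 2.46 (1.22 ± 0.10), were also higher in KO, as was H19 at 16.1 and 75.1 (2.17 ± 0.16). KO was lower for Tbx5, at 16.4 and 0.186 (−3.86 ± 0.09), the antioxidant enzyme gene Sod3, at 16.6 and 1.02 (−3.09 ± 0.16), the collagen gene Col10a1, at 30.9 and 4.33 (−2.57 ± 0.10), and Xist, at 162 and 33.9 (−2.22 ± 0.21).

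Under DAC 17 lists passed in camera. Germline genes were higher in KO in 11 of 12 cases and lower in 1 (median 0.847, adjusted p = 1.23e-06, and adjusted p = 0.0983 with an estimated correlation). The exception was Xlr3b, whose value is uncertain because it has near-identical copies. Germline genes that passed the filter only through KO DAC libraries were bound to be higher in KO. Imprinted genes (8 of 21 higher, 3 lower, 0.13, adjusted p = 0.0132), Hox genes (9 of 24 higher, 4 lower, 0.207, adjusted p = 0.0187), neural markers (3 of 5 higher, 0 lower, 0.473, adjusted p = 0.0111) and sex-linked genes (4 of 5 higher, 1 lower, 2.397, adjusted p = 0.000111) were shifted upward. Their values were adjusted p = 0.159 to 0.273 with an estimated correlation. Glycolysis genes (12 of 21 higher, 1 lower, 0.35, adjusted p = 6.65e-05), G2/M genes (7 of 27 higher, 0.137, adjusted p = 0.00493), epithelial markers (4 of 8 higher, 0.507, adjusted p = 0.0271) and stress genes (6 of 22 higher, 0.13, adjusted p = 0.04) were as well, at adjusted p = 0.322 to 0.46 with an estimated correlation. Shifted downward were interferon-stimulated genes (14 of 35 lower, 1 higher, −0.246, adjusted p = 6.01e-05), inflammatory genes (13 of 25 lower, −0.294, adjusted p = 2.99e-05), p53 targets (14 of 29 lower, 1 higher, −0.313, adjusted p = 0.000682) and chondrocyte markers (6 of 9 lower, 1 higher, −0.748, adjusted p = 0.00253), with adjusted p = 0.124 to 0.277 with an estimated correlation. Collagen genes (15 of 27 lower, 6 higher, −0.398, adjusted p = 0.000212), cholesterol genes (13 of 21 lower, −0.339, adjusted p = 7.97e-06), immediate early genes (10 of 18 lower, 3 higher, −0.336, adjusted p = 0.0103) and smooth-muscle genes (7 of 17 lower, 1 higher, −0.307, adjusted p = 0.0302) were too, with adjusted p = 0.314 to 0.46 with an estimated correlation. Col3a1 was at 50.9 FPKM in WT and 23.2 in KO (−1.11 ± 0.12) and Hmgcs1 at 31.8 and 19.9 (−0.65 ± 0.06). With values adjusted over the list alone, 17 interferon-stimulated, 16 p53, 15 inflammatory, 17 collagen, 12 immediate early, 8 smooth-muscle and 7 chondrocyte genes were lower, and 13 glycolysis, 10 Hox and 7 stress genes higher. For adipocyte markers, not called, the median was −0.303, the mean 0.25 and the test downward.

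The interaction of DAC with genotype asks whether DAC changed a gene by a different amount in KO than in WT. It was called upward for 2032 genes and downward for 1928, 370 and 796 by at least 2-fold. Without KO DMSO replicate 1 the upward count was 1345. Xist was called upward (4.44 ± 0.33, adjusted p = 3.5e-05), rising with DAC in KO and staying at 175 and 162 FPKM in WT. The water-channel gene Aqp1 went from 52.3 to 34 FPKM in WT and from 15.5 to 54.4 in KO (interaction 2.35 ± 0.08, adjusted p = 9.4e-07). The adipocyte regulator Pparg went from 3.78 to 2.72 and from 0.549 to 3.07 (1.76 ± 0.13), and Penk from 104 to 26.1 and from 6.68 to 11.4 (2.63 ± 0.23). In the other direction the complement gene C3 went from 2.77 to 11.7 FPKM in WT and from 81.6 to 8.91 in KO (−4.83 ± 0.15, adjusted p = 7.8e-07). Plxna4 (−4.45 ± 0.14) and Aldh1a2 (−4.31 ± 0.15) fell in KO from levels not seen in WT. Lrrn4, listed at 0 in both WT DMSO libraries and at 0.111 in WT DAC, went from 58.2 to 2.02 FPKM in KO.

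By list, the response to DAC was more positive in KO for interferon-stimulated genes (23 of 35 called upward, 0 downward, median 0.85, camera adjusted p = 4.14e-11, and adjusted p = 0.0983 with an estimated correlation). The same direction was found for germline genes (9 of 12, 0.898, adjusted p = 5.86e-05), p53 targets (15 of 29, with 3 downward, 0.482, adjusted p = 0.000114), G2/M genes (11 of 27, 0.323, adjusted p = 2.18e-05), cholesterol genes (12 of 21, 0.429, adjusted p = 6.65e-05) and sex-linked genes (5 of 5, 0.617, adjusted p = 0.00132), with adjusted p = 0.146 to 0.389 with an estimated correlation. The sex-linked members other than Xist are Y-linked and near absent in WT, so theirs is the response in KO alone. Isg15 (1.72 ± 0.35) and Cdkn1a (1.61 ± 0.18) started lower in KO DMSO and ended at 106 and 70.5 FPKM in KO DAC against 150.4 and 101.1 in WT DAC. Inflammatory genes (11 of 25 downward, 3 upward, −0.351, adjusted p = 0.00451), glycolysis genes (9 of 21 downward, −0.455, adjusted p = 2.87e-05) and epithelial markers (4 of 8 downward, −0.545, adjusted p = 0.0271) responded less positively, with adjusted p = 0.315 to 0.328 with an estimated correlation. Of the 4 epithelial genes, Krt7 (−3.347) and Krt18 (−2.61) are also mesothelial markers, most of which fell in the same KO DAC libraries. Spp1 rose in both genotypes but less in KO (−1.30 ± 0.14). Hox genes, not called, had 11 of 24 upward and 10 downward, a median of 0.568 and a mean of 0.038. Counted with values adjusted over the list alone, 24 interferon-stimulated, 19 p53, 15 G2/M and 13 cholesterol genes were called upward and 12 glycolysis genes downward. KO against WT in DMSO, DAC in KO and the interaction all rest on the same 2 KO DMSO libraries. On the first principal component these lay at 66.2 and 66.8, and the others from −29.9 to −1.9. The interferon, p53, G2/M, cholesterol, glycolysis and epithelial lists had shifted the opposite way in KO against WT in DMSO. Their interactions are thus not separate evidence of a different response to DAC.

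**Figure D2:**
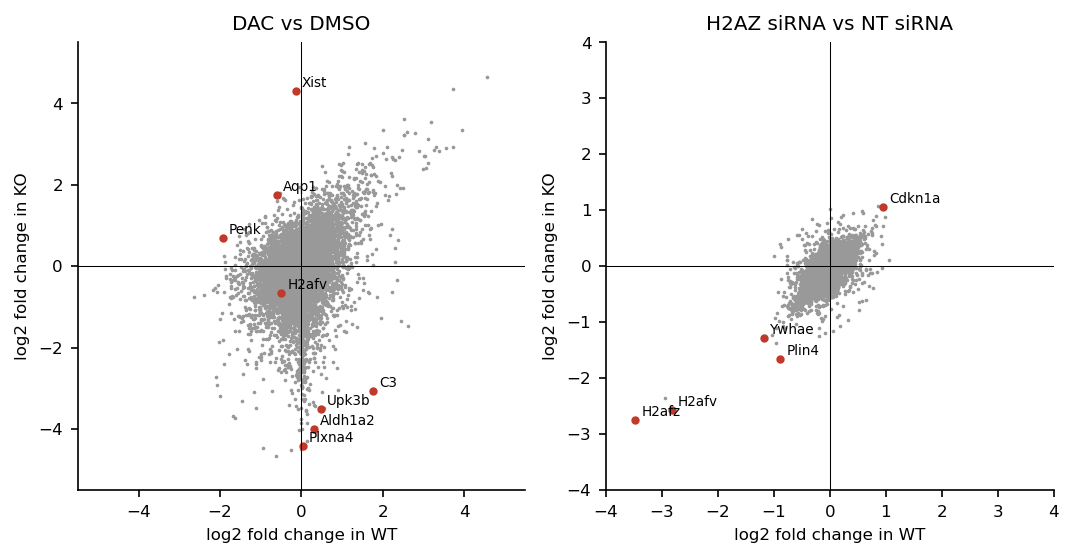
Log2 fold change of every gene in WT against that in KO, for DAC (left, r = 0.429 over 16434 genes) and for H2AZ siRNA (right, r = 0.672 over 12668 genes); named genes such as Xist (4.29 in KO) are marked.

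Comparing KO with WT under NT siRNA repeats the genotype question in the second experiment. Of 12668 genes tested, 3004 were higher and 5122 lower in KO (3 libraries per group), 256 and 379 by at least 2-fold. The median of all genes was −0.096, and after median centring 4028 were higher and 4127 lower. Upk3b was at 0.00321 RPKM in WT and 64.9 in KO (6.04 ± 0.06, adjusted p = 9.1e-14), and Upk1b at 0 in all 3 WT libraries and 29.3 in KO. The retinal-oxidising enzyme gene Aldh1a1 was at 0.0771 and 23.2 (4.50 ± 0.06) and Dcn at 1.44 and 22 (3.24 ± 0.23). KO was lower for the gap-junction gene Gjb2, at 33 and 2.72 RPKM (−3.20 ± 0.09, adjusted p = 3.4e-10), and the prostaglandin synthase gene Ptgs2, at 86.8 and 14.3 (−2.52 ± 0.12). So it was for Thbs1, at 765 and 160.1 (−2.25 ± 0.08). Xist was at 5 RPKM in WT and 0.000479 in KO (−2.57 ± 0.12). The WT DMSO libraries, normalised separately, had 169.7 and 181 FPKM of Xist. The cause of the much lower level in WT NT was not tested.

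With NT siRNA 7 lists passed between the genotypes. Smooth-muscle genes were lower in KO in 13 of 16 cases and higher in 1 (median −0.712, camera adjusted p = 0.000399), Cnn1 at 121 RPKM in WT and 31 in KO. Also lower were G2/M genes in 19 of 27 with 1 higher (−0.384, adjusted p = 0.00247), interferon-stimulated genes in 23 of 31 with 2 higher (−0.331, adjusted p = 0.00574) and p53 targets in 18 of 29 with 3 higher (−0.38, adjusted p = 0.0389). These had adjusted p = 0.592 to 0.826 with an estimated correlation. Adipocyte markers were higher in 5 of 5 cases (0.997, adjusted p = 0.000456), Cebpa at 0.311 and 2.58 RPKM. Also higher were glycolysis genes in 14 of 22 with 3 lower (0.282, adjusted p = 0.000485) and sex-linked genes in 4 of 5 with Xist lower (1.595, adjusted p = 0.0163). These had adjusted p = 0.206 to 0.592 with an estimated correlation. Cholesterol genes (10 of 21 lower, 3 higher, −0.054) and H2A.Z genes (6 of 18 higher, 5 lower, median −0.036 with the test upward) were not called. Counts adjusted over the list alone were the same for all 7 called lists.

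H2AZ siRNA against NT siRNA in WT asks which genes change in WT cells given an siRNA against H2A.Z. Effects of the siRNA on other transcripts were not separated from those of H2A.Z loss, here or in KO. It raised 618 genes and lowered 1315 (3 libraries per group), 0 and 6 by at least 2-fold. The raised count was 406, 347 and 329 without WT NT replicate 3, WT H2AZ replicate 1 and WT H2AZ replicate 3, and the lowered count 778, 865 and 876 without WT H2AZ replicates 1, 2 and 3. After median centring the counts were 1063 and 1184. Beyond H2afz and H2afv, the 14-3-3 gene Ywhae (chromosome 11) fell from 119.9 to 52.7 RPKM (−1.17 ± 0.05, adjusted p = 5.8e-08) and the heterochromatin protein gene Cbx1 from 13.9 to 8.14 (−0.70 ± 0.07). Cdkn1a rose from 29.4 to 57.7 RPKM (0.95 ± 0.06, adjusted p = 3.1e-06), the cyclin gene Ccng1 from 116 to 204 (0.81 ± 0.10), Sesn2 from 5.31 to 9.56 (0.75 ± 0.07) and the growth-factor receptor gene Gfra1 from 2.28 to 5.21 (0.92 ± 0.08).

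With H2AZ siRNA in WT, p53 targets rose in 20 of 29 cases and fell in 1 (median 0.433, camera adjusted p = 1.64e-17, and adjusted p = 0.206 with an estimated correlation). Stress genes passed upward (4 of 22 higher, 1 lower, 0.073, adjusted p = 0.00189, and adjusted p = 0.206 with an estimated correlation). Interferon-stimulated genes passed downward (6 of 31 lower, 0 higher, −0.194, adjusted p = 0.00189, and adjusted p = 0.826 with an estimated correlation), Ifit3 falling from 14.8 to 8.6 RPKM. H2A.Z genes also did (5 of 18 lower, 0 higher, −0.065, adjusted p = 0.0273, and adjusted p = 0.592 with an estimated correlation), but that list holds the siRNA's own targets. Without H2afz and H2afv it was not called (3 of 16 lower, −0.057, adjusted p = 0.461). Adjusted over the list alone, 22 p53 and 7 stress genes were higher and 8 interferon-stimulated genes lower.

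H2AZ siRNA against NT siRNA in KO asks the same in KO cells. It raised 831 genes and lowered 2404 (3 libraries per group), 3 and 16 by at least 2-fold. The raised count was 553, 478 and 427 without KO NT replicate 2, KO NT replicate 3 and KO H2AZ replicate 1, and the lowered count 1513 without KO H2AZ replicate 2. After median centring the counts were 1709 and 1686. Ywhae fell from 110.0 to 44.5 RPKM (−1.29 ± 0.05, adjusted p = 2.0e-08). So did the lipid-droplet gene Plin4 from 8.6 to 2.07 (−1.66 ± 0.12), the matrix gene Ccn5 from 20.9 to 7.5 (−1.38 ± 0.15) and Cbx1 from 11.7 to 7.2 (−0.63 ± 0.07). Cdkn1a rose from 28.4 to 60.2 RPKM (1.05 ± 0.06, adjusted p = 9.4e-07), Mdm2, whose product degrades p53, from 7.55 to 15.8 (0.96 ± 0.16), the collagenase gene Mmp13 from 11.4 to 23.1 (0.95 ± 0.13) and the muscle actin gene Acta1 from 3.01 to 7.46 (1.07 ± 0.11).

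In KO, p53 targets rose with H2AZ siRNA in 22 of 29 cases and fell in 1 (median 0.414, camera adjusted p = 1.6e-16), stress genes rose in 11 of 22 with 1 lower (0.145, adjusted p = 5.07e-06) and immediate early genes in 5 of 16 with none lower (0.1, adjusted p = 0.00189), each with adjusted p = 0.206 with an estimated correlation. Inflammatory genes passed upward (7 of 22 higher, 3 lower, 0.121, adjusted p = 0.00574) and interferon-stimulated genes downward (12 of 31 lower, 2 higher, −0.213, adjusted p = 0.0256), with adjusted p = 0.592 and adjusted p = 0.826 with an estimated correlation. Isg15 fell from 31.2 to 19.8 RPKM and Rtp4 from 13.2 to 7.88. H2A.Z genes were not called as a list (7 of 18 lower, 1 higher, −0.128, adjusted p = 0.12). Adjusted over the list alone, 23 p53 and 14 stress genes were higher and 4 inflammatory genes lower.

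KO against WT under H2AZ siRNA asks how the genotypes differ once H2A.Z transcripts are depleted. KO was higher for 2563 genes and lower for 5409 (3 libraries per group), 230 and 351 by at least 2-fold. The median of all genes was −0.121, so changes are relative to that shift, and after median centring 4037 were higher and 3924 lower. Aldh1a1 was at 0.0398 RPKM in WT and 29.3 in KO (4.87 ± 0.06, adjusted p = 1.6e-13), Podxl at 0.14 and 15.4 (3.85 ± 0.08), and Upk3b at 0 in all 3 WT libraries and 51.5 in KO. KO was lower for Gjb2, at 35.8 and 2.82 (−3.27 ± 0.09, adjusted p = 2.3e-10), Thbs1, at 637 and 119 (−2.41 ± 0.08), and the decoy-receptor gene Tnfrsf11b, at 7.95 and 0.683 (−2.42 ± 0.08).

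Of the lists under H2AZ siRNA, interferon-stimulated genes (19 of 31 lower in KO, 2 higher, median −0.493, camera adjusted p = 0.0338), p53 targets (19 of 29 lower, 1 higher, −0.428, adjusted p = 0.0224) and smooth-muscle genes (13 of 16 lower, 1 higher, −0.642, adjusted p = 0.000456) were lower. S-phase genes (14 of 32 higher, 10 lower, 0.086, adjusted p = 0.0396), glycolysis genes (14 of 22 higher, 4 lower, 0.302, adjusted p = 0.000399), adipocyte markers (4 of 5 higher, 0.801, adjusted p = 0.000834) and sex-linked genes (4 of 5 higher, 1 lower, 1.428, adjusted p = 0.0103) were higher. All 7 lost the call, with adjusted p = 0.206 to 0.826 with an estimated correlation. Among S-phase genes Cdt1 was at 15.4 RPKM in WT and 25.8 in KO (0.71 ± 0.08) and Ccne2 at 25.1 and 12.9 (−0.91 ± 0.13). Adjusted over the list alone, 20 interferon-stimulated and 11 S-phase genes were lower, and 15 glycolysis genes higher with 5 lower.

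The interaction of H2AZ siRNA with genotype asks whether the siRNA acted differently in KO. limma called 1 gene upward, H2afz (0.72 ± 0.08, adjusted p = 0.012), and 0 downward, with 1095 genes at an unadjusted p under 0.05. A voom fit called 2 and 0, and a voom fit with median-ratio scaling 13 and 5. The H2afz call was absent without WT NT replicate 1 (adjusted p = 0.0627), WT NT replicate 2 (0.0574), WT H2AZ replicate 1 (0.0562) or WT H2AZ replicate 2 (0.0679), with an upward count of 0 in each case. The upward count was 2 without WT H2AZ replicate 3, and the downward count 1 without WT NT replicate 3 or KO H2AZ replicate 3. Of the lists, 5 passed in camera with no member called: G2/M genes (median 0.079, adjusted p = 5.18e-06), inflammatory genes (0.144, 0.00234), immediate early genes (0.044, 0.00574), stress genes (0.046, 0.00977) and collagen genes (−0.087, 0.0111), with adjusted p = 0.247 to 0.826 with an estimated correlation and 0 lists by fry.

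**Figure D3:**
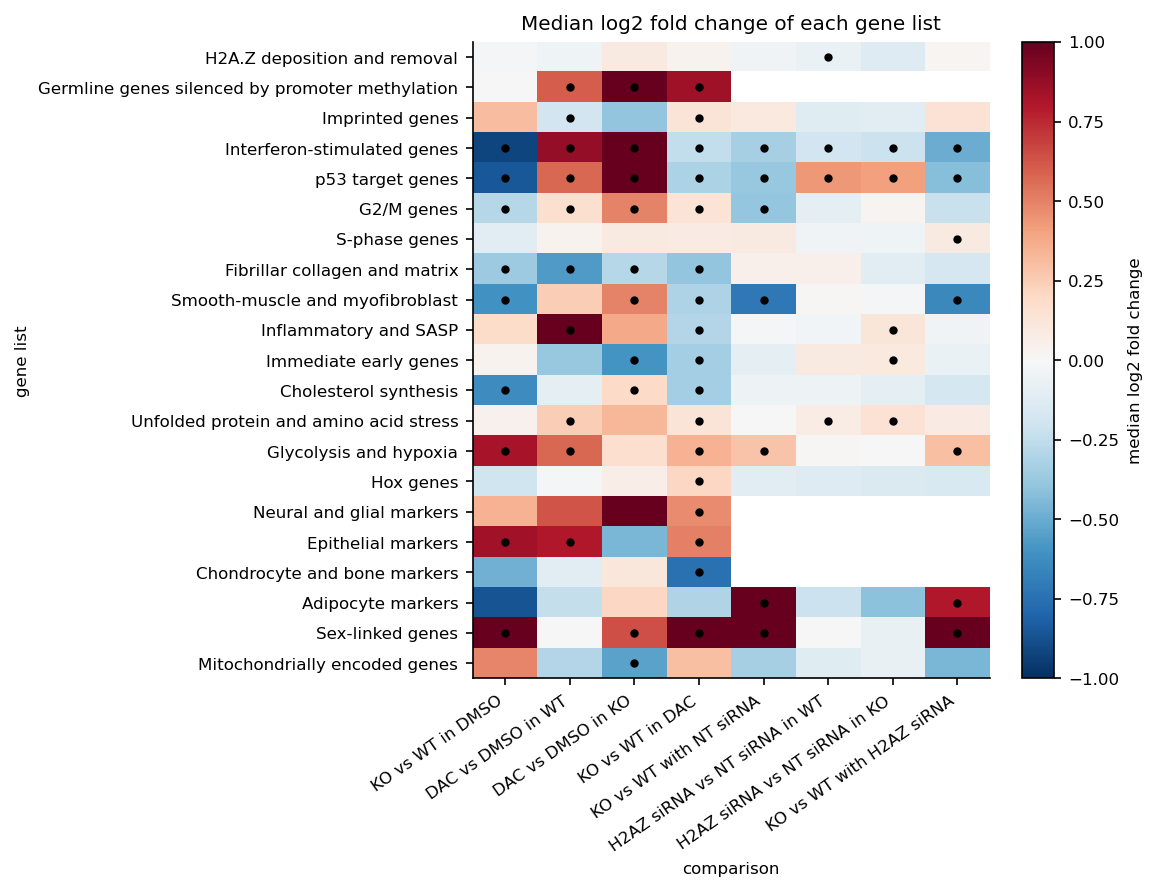
Median log2 fold change of each gene list in 8 comparisons, with dots on lists that passed in camera with its preset correlation; interferon-stimulated genes ran from −0.915 (KO against WT in DMSO) to 1.918 (DAC in KO), beyond the colour scale. No called median changed sign under median centring, voom with median-ratio totals or chromosome centring, but 36 of 83 moved by over 1.5 times under at least one of these, such as S-phase genes for KO against WT with H2AZ siRNA (0.086, and 0.214 with median centring).

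Setting the effects side by side asks whether the genotypes share a response and whether both experiments show one KO effect. Across 12668 genes the H2AZ siRNA effects in WT and KO correlated at r = 0.672 (rho = 0.661), with 326 genes higher in both, Cdkn1a included, 1049 lower in both, Ywhae included, and 0 opposite. The DAC effects in WT and KO correlated at r = 0.429 (rho = 0.436) over 16434 genes, with 1584 higher in both, Apob and Oas3 included, 1148 lower in both and 471 opposite. The KO effect in DMSO correlated with that under NT siRNA at r = 0.366 (rho = 0.133) over 11906 genes. Of 3652 genes called in both, 62.3% went the same way, with 805 higher in both against 540.7 for independent calls and 1469 lower in both against 1266.1. Upk3b, Podxl and Dcn were higher and Xist lower in both, whereas Spp1 was higher in KO in DMSO (0.84 ± 0.10) and lower under NT siRNA (−2.06 ± 0.14). Genes are not independent replicates. Genes lower in KO DMSO, taken as a set of 3067, had a median of −0.088 with H2AZ siRNA in KO against −0.045 for the others (adjusted p = 0.0416 by camera and adjusted p = 0.938 with an estimated correlation). In WT the same set was not called (−0.041 against −0.031, adjusted p = 0.756), and its interaction was (−0.058 against −0.019, adjusted p = 0.00295, and adjusted p = 0.938 with an estimated correlation). The set higher in KO DMSO was not called with H2AZ siRNA in WT (adjusted p = 0.404) or KO (adjusted p = 0.175).

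A check chosen after the data were seen placed the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty at 1 or more in every KO library and under 0.1 in every WT library of both tables. Ddx3y was at 3.08 FPKM in KO DMSO and 0.00627 in WT DMSO, and at 5.06 RPKM in KO NT against 0 in all WT NT libraries. Of 18 listed mesothelial marker genes, also chosen afterwards, 16 passed the filter in the DAC table and 14 of these were higher in KO DMSO. The listed marker Calb2 was at 0 in every KO library of the DAC table and every KO NT library. It did not pass the filter and is in none of these counts. Of the 14, 13 fell with DAC in KO (median −3.36) and Msln did not (0.10). Krt8 and Krt19 were not called in KO DMSO and rose with DAC in KO (1.671 and 1.845). All 15 markers measured in the siRNA table were higher in KO under NT siRNA. Most markers in either table passed the filter only through KO libraries, which fixed their direction. In the siRNA table Aldh1a2, Krt18, Krt19 and Msln also reached it in WT. Chromosome medians of the KO effect in DMSO ran from −0.443 on chromosome 10 to 0.168 on chromosome 11 and their SD of 0.1596 exceeded the highest of 1000 shuffles of genes over chromosomes (0.0349). Every other comparison also exceeded its shuffles, with a smaller SD, such as DAC in WT (0.0345 against 0.02) and H2AZ siRNA in WT (0.0133 against 0.0123). For DAC in KO the medians ran from −0.096 to 0.265, and for KO against WT under NT siRNA from −0.313 to 0.173. The medians of the KO effect in DMSO correlated with those under NT siRNA at 0.371, chromosome 10 being at −0.082 there and at −0.119 for KO against WT in DAC.

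**Figure D4:**
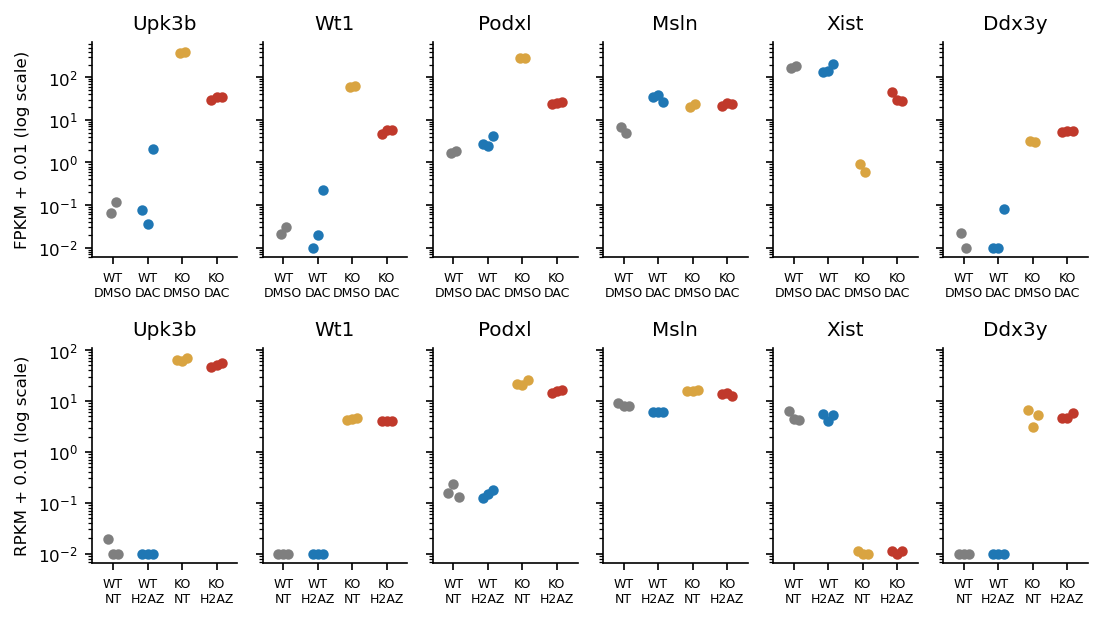
Mesothelial markers (Upk3b, Wt1, Podxl, Msln), Xist and the Y-linked Ddx3y in every library on a log scale with 0.01 added; Upk3b averaged 384 FPKM in KO DMSO and 32.9 in KO DAC. The tables were normalised separately.

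**Figure D5:**
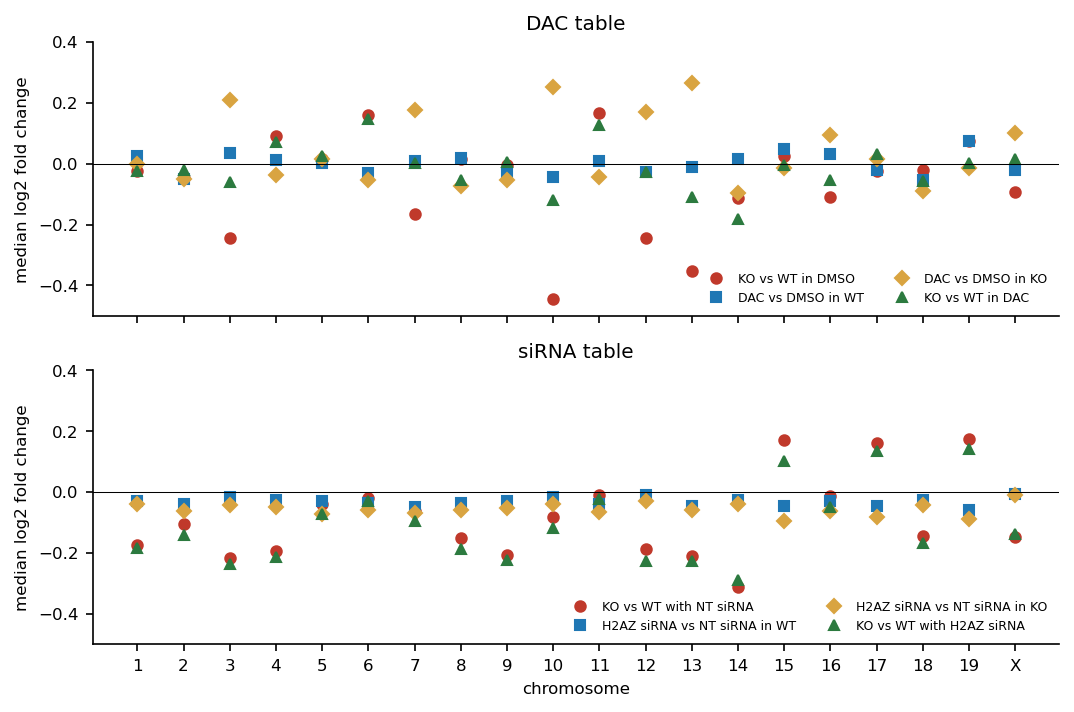
Median log2 fold change of the genes on each chromosome in 8 comparisons; the KO effect in DMSO was −0.443 on chromosome 10 and 0.168 on chromosome 11.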

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

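Chosen after their results were seen were the tests of mesothelial markers, with and without those raised by DAC in WT. So were those of Y-linked genes and of genes confined to WT, and the chromosome medians themselves. Set before their outcome were the test of gene length and level and that of proximal and distal parts of each chromosome. The test of Tsix and the counts of splits were too.

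These results were marked because the effect of a treatment differed between KO and WT in a test of the difference itself. The DAC interaction was called upward for 2032 genes and downward for 1928. It shares the KO DMSO libraries with the KO effect in DMSO, so in part it mirrors that difference. Among genes, Xist (4.44), Penk (2.63), Aqp1 (2.35) and Npnt (2.33) were upward and C3 (−4.83), Plxna4 (−4.45), Lrrn4 (−4.45) and Aldh1a2 (−4.31) downward. Lrrn4 was listed at 0 in WT DMSO, so its value rests on the pseudocount. Plxna4 and Aldh1a2 were very low there too, so their values mostly reflect the fall in KO. Among lists, medians were 0.898 for germline genes, 0.85 for interferon-stimulated genes, 0.482 for p53 targets, 0.323 for G2/M genes, 0.429 for cholesterol synthesis and 0.617 for sex-linked genes, and −0.351 for inflammatory genes, −0.455 for glycolysis and hypoxia and −0.545 for epithelial markers. The sex-linked list holds Y-linked genes near absent in WT, for which the difference is the response in KO alone. For H2AZ siRNA 1 gene was called, H2afz (0.72). The lists G2/M (0.079), collagen and matrix (−0.087), inflammatory (0.144), immediate early (0.044) and unfolded-protein stress genes (0.046) were marked too, without a called member. No list kept its call with an estimated correlation.

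The KO effect in DMSO shifted whole chromosomes, with medians from −0.443 on chromosome 10 to 0.168 on chromosome 11. Gene length and level as the whole cause were argued against, since removing their trend left 88.9% of the SD of the 20 medians (0.16 before, 0.142 after). The genes of each chromosome, ordered by position, were cut at the middle gene into a proximal and a distal part. The medians of these parts correlated at 0.938, with 16 of 20 of the same sign and 0.915 to 0.951 without any 1 chromosome. This goes with gain or loss of whole chromosomes in part of a culture. Under NT siRNA the shifts recurred only in part, since the medians there correlated at 0.371 with those in DMSO. The medians in DMSO correlated at −0.846 with those of DAC in KO. That comparison holds the KO DMSO libraries with the opposite sign, which by itself makes the correlation negative, so it cannot show whether the shifts recurred. KO against WT in DAC shares no library with the KO effect in DMSO. Chromosome 10 was at −0.119 for KO against WT in DAC and at −0.082 under NT siRNA, and chromosome 11 at 0.126 and −0.011. The next lowest in DMSO, chromosomes 13, 12 and 3 (−0.354, −0.245 and −0.244), were at −0.108, −0.026 and −0.059 in DAC. The next highest, chromosomes 6 and 4 (0.16 and 0.09), were at 0.148 and 0.072. These kept their sign in DAC, each at a smaller size, whereas chromosome 7 was at −0.164 in DMSO and 0.001 in DAC. Gain or loss of whole chromosomes is a hypothesis, since DNA content was not measured, and other causes that act on whole chromosomes were not tested. After centring each chromosome, 3221 genes were higher and 3133 lower in KO DMSO.

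Of the mesothelial markers, 14 were higher in KO DMSO and 13 of these lower with DAC in KO, including Upk3b (384 to 32.9 FPKM), Podxl (287 to 25) and Wt1 (61.4 to 5.48). Msln was the exception among them. Krt8 and Krt19 were not called in KO DMSO and rose with DAC in KO (1.671 and 1.845). The list shares Krt7, Krt8, Krt18 and Krt19 with the epithelial list, and 3 of the 16 measured were at 1 FPKM or more in WT DMSO. The listed marker Calb2 was at 0 in both KO DMSO libraries and is not among the 16. A smaller share of 1 cell type in the KO DAC cultures, as the whole cause, is argued against, because it would lower all markers alike, while their changes had an SD of 1.27 against a median standard error of 0.14. Much of that SD came from Msln (0.105) and Krt18 (−0.766), which DAC raised in WT. Without the 4 markers that DAC raised in WT, the other 10 ran from −4.52 to −2.8, with an SD of 0.55 against a median standard error of 0.13. Several markers did fall alike, Upk3b by −3.509, Pkhd1l1 by −3.391 and Wt1 by −3.273, so a smaller share together with a change of expression stays open, and mesothelial cells in the KO cultures are a candidate source that was tested in no other way. All 4 Y-linked genes were at 1 or more in every KO library and under 0.1 in every WT library. The knockout and a different sex and origin of the cultures thus cannot be told apart for these markers. The same design holds for every other difference between KO and WT.

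Xist was near absent in KO DMSO and rose in KO DAC to 33.9 FPKM, with the Y-linked genes present in the same libraries. WT cells or reads mixed into the KO DAC libraries are argued against: 20 genes at 10% or less of their WT level in KO DMSO, a limit loosened after a stricter one left Tbx5 alone, rose from KO DMSO to KO DAC by a median of 7.92% of the gap between KO DMSO and WT DAC against 20.6% for Xist. Shares ran from −16.68 to 58.38%, with 7 genes at or over that of Xist, and Svep1, Sfrp2 and Thbd were lower in KO DAC than in KO DMSO. A mixture would still leave each gene in KO DAC at 20.6% or more of its WT DAC level, and 12 of the 20 were under that, Tbx5 at 1.1%, Sall1 at 3.7% and Sod3 at 6.2%. Tsix was at no more than 0.00046 of Xist, but the strand setting is not given, and unstranded counts would list Tsix reads over Xist as Xist, so reads of Tsix stay open. Activation of Xist by loss of DNA methylation in KO cells stays a candidate explanation that these data did not test, since methylation was not measured.

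Other splits of the libraries were counted for comparisons with 3 libraries per group. In each of the 5, only 1 of 10 splits, the real one, called as many genes as the real split, and 10 splits are too few for a share under 0.05. The real counts were 3730 for KO against WT in DAC, 8126 with NT siRNA, 1933 for H2AZ siRNA in WT, 3235 for H2AZ siRNA in KO and 7972 for KO against WT with H2AZ siRNA, and the highest other splits called 1, 1, 0, 1 and 0. For the siRNA interaction, 4 of 100 splits, the real one included, called at least the 1 gene of the real split, and the highest other split called 5. A real count of 1, which was lost on leaving out any of several WT libraries, is too low for the splits to decide anything. These splits were drawn so that each group kept at least 2 libraries under its own siRNA.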

How the results depend on the processing

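The voom fits, the fit without both libraries that stand apart, chromosome centring, the alternatives of the DAC and H2AZ siRNA correlations, the fit of KO NT and KO H2AZ siRNA alone with a replicate block, the list tests with a block and the H2A.Z list without H2afz and H2afv were chosen after the data were seen. For none of the values below was the cause tested beyond what the setting itself removes; the cause was not tested.

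Counts that moved by over 1.5 times are given here. A 2-fold minimum, which by construction keeps fewer genes, left higher and lower counts of 997 and 716 (KO against WT in DMSO), 319 and 277 (DAC in WT), 583 and 913 (DAC in KO), 191 and 172 (KO against WT in DAC), 370 and 796 (DAC interaction), 256 and 379 (KO against WT with NT siRNA), 0 and 6 (H2AZ siRNA in WT), 3 and 16 (H2AZ siRNA in KO), 230 and 351 (KO against WT with H2AZ siRNA) and 0 higher for the siRNA interaction. A filter at 5, which tests fewer genes, left 2248 lower for DAC in KO, 1985 higher for KO with NT siRNA and 1577 lower for H2AZ siRNA in KO. Higher counts with H2AZ siRNA in WT became 1063 (median centring), 1138 (voom, median-ratio totals) and 1119 (chromosome centring), in KO 1709, 1867 and 1733, and 476 with only the groups compared, and for KO with H2AZ siRNA 4037 (median centring) and 4023 (voom, median-ratio totals). The siRNA interaction's count of 1 higher became 0 with no filter, 2 with a filter at 5, 3 with median centring, 2 with the replicate block, 2 with voom, 13 higher and 5 lower with voom and median-ratio totals, 0 without both libraries that stand apart and 3 with chromosome centring.

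Leaving out 1 library gave 1325 to 2612 higher and 1166 to 2127 lower for DAC in WT, 1345 to 2036 higher for the DAC interaction, 329 to 511 higher and 778 to 1048 lower for H2AZ siRNA in WT, 427 to 1020 higher and 1513 to 2426 lower for H2AZ siRNA in KO, and 0 to 2 higher and 0 to 1 lower for the siRNA interaction.

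Replicate numbers paired the KO NT with the KO H2AZ siRNA libraries. With them as a block H2AZ siRNA in KO had 1019 higher and 2692 lower genes, or 755 and 1966 with only those groups fitted, and the 5 lists of the main fit were called in both. Of its named genes, Flt1 lost its call with the block (adjusted p = 0.0507), and Flt1, Kdr, Ccnb1, Bub1b and Gins2 did with only those groups (0.0549 to 0.111); no other named call of that comparison changed. Elsewhere the numbers did not pair the samples. Libraries that stand apart correlated across genotypes. WT DAC replicate 3 and KO DAC replicate 1 did at 0.35, and WT NT replicate 1 and KO NT replicate 1 at 0.32. Whether they share a batch was not tested. Equal numbers correlated at −0.09 to 0.01 between WT NT and WT H2AZ siRNA, 0.02 to 0.32 between WT NT and KO NT, 0.04 to 0.07 between WT and KO H2AZ siRNA and −0.22 to 0.13 between WT and KO DAC, and not every library correlated best with its own number. With the block, counts were 721 and 1543 for H2AZ siRNA in WT, 3040 and 5316 for KO with NT siRNA, 2604 and 5578 for KO with H2AZ siRNA, 1441 and 1510 for KO against WT in DAC and 1616 and 1651 for the DAC interaction.

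No list was called with an estimated correlation in any of the 10 comparisons (0 each). With fry the counts were 18 (KO in DMSO), 19 (DAC in KO), 14 (DAC interaction), 12 (KO with NT siRNA), 9 (H2AZ siRNA in KO), 13 (KO with H2AZ siRNA) and 0 (siRNA interaction), and fry reversed adipocyte markers for KO against WT in DAC (0.00206 upward) and Hox genes in the DAC interaction (6.07e-06 downward). Of 83 called list medians, 7 moved by over 1.5 times with median centring, 17 with chromosome centring and 29 with voom and median-ratio totals, which adds no pseudocount of 1, and 0 changed sign. Examples with chromosome centring were G2/M genes for KO with NT siRNA (−0.384 to −0.213) and Hox genes for KO against WT in DAC (0.207 to 0.095), and with median centring H2A.Z genes in WT (−0.065 to −0.035). Of the sets of genes changed in one table and tested in the other, 10 were called, and 0 with an estimated correlation.

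The KO effects in DMSO and with NT siRNA correlated at 0.482 with a pseudocount of 0.1, 0.323 with a filter at 5 and 0.343 to 0.38 leaving out 1 library. The DAC effects in WT and KO gave 0.378, 0.475, 0.442 without both libraries that stand apart and 0.403 to 0.434 leaving out 1. The H2AZ siRNA effects gave 0.561, 0.751, 0.637 and 0.634 to 0.664.

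Reversals of named genes were confined to values near 0 and Tet1. Tet1, called lower in KO in DMSO (−0.40), was at 0.022 with chromosome centring (adjusted p = 0.905). H2afz with DAC in WT was at −0.01 with chromosome centring and −0.042 to 0.198 leaving out 1 library, and for KO against WT in DAC at −0.003 to 0.276. H2afv for KO against WT in DAC was at −0.039 without both libraries that stand apart, −0.111 with chromosome centring and −0.073 to 0.076 leaving out 1. H2afz for KO against WT with NT siRNA was at 0.039 (median centring), 0.06 (voom, median-ratio totals) and 0.17 (chromosome centring, adjusted p = 0.0189). Anp32e with H2AZ siRNA was at 0.003 in WT without both libraries that stand apart, −0.112 to 0.003 leaving out 1, and −0.021 to 0.183 in KO. Of 750 results for named genes, 25 lost their call with the block, 45 with no filter, 9 with a pseudocount of 0.1, 12 with median centring, 8 with voom, 15 with voom and median-ratio totals, 23 without both libraries that stand apart, 30 with chromosome centring and 349 with a 2-fold minimum. Outside the interactions 37 did with only the groups compared, and over all fits that left out 1 library 334 calls were lost.

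Depth limits low values: 1 read in a gene of 1 kb is 0.0271 to 0.0364 FPKM, so levels of Wt1 in WT DMSO (0.0155) or of germline genes such as Dazl and Tex19.1 without DAC rest on few reads, and the DAC interactions of Dazl and Tex19.1 did not pass with voom (adjusted p = 0.946 and 0.279). With 2 DMSO libraries per genotype, 35.8% of 1.5-fold interactions were recovered in simulated data, which held no libraries that stand apart.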

Other observations

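No test in this part was chosen after its result was seen, and the genes come from lists fixed before the data were examined.

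Among DNA-methylation and silencing genes, responses to DAC had both directions. Dnmt3a fell from 6.17 to 3.86 FPKM in WT (limma log2 fold change −0.56 ± 0.10) and from 6.62 to 3.18 in KO (−0.87 ± 0.10), Tet3 fell from 16.5 to 11.5 in WT (−0.48 ± 0.06) and from 23.4 to 11.1 in KO (−1.01 ± 0.06), and Suv39h1 rose from 8.03 to 10.2 in WT (0.31 ± 0.06) and from 7.86 to 15.3 in KO (0.88 ± 0.06). Uhrf1 was at 35.7 and 36.8 FPKM in WT and went from 35.6 to 52.5 in KO (interaction 0.51 ± 0.08, limma adjusted p = 0.0018).

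The Anp32e relatives Anp32a and Anp32b moved apart with DAC in WT. Anp32a fell from 22.3 to 15.9 FPKM in WT (−0.46 ± 0.07) and from 27.8 to 15.8 in KO (−0.79 ± 0.07), whereas Anp32b rose in WT (0.47 ± 0.07).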
